A study of Homo sapiens with 8 samples.

How the data were processed

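Gene expression was measured by microarray in the human melanoma cell lines 4L and 5B1. Per the labels' protocols, 250000 cells grown with 5% fetal bovine serum were transfected by lipofection with 50 nM of a scrambled oligonucleotide or of miR-30d and were harvested after 48 h. Total RNA was column-purified, and 100 ng was converted to biotin-labelled cRNA with an Affymetrix kit that primes at the poly(A) end, per the labels' protocols. There were 8 arrays in 4 groups of 2 repeats. The series' design text calls the duplicates biological. Nothing in the sources used here says more about how the repeats were made, so p-values measure the spread between these arrays only.

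The deposited table holds 1 intensity per probe set and array, which the authors summarised with RMA per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays and combines the probes of a set; its software version is not given in the sources used here. The values lay on a linear scale from 5.54 to 28719, and log2 was taken before any test. The medians of the 8 arrays ran from 39.8 to 41.7. No further normalization was applied. Equalising the arrays removes any change shared by all genes, so fold changes are relative to the other genes of an array. The number of arrays limits the precision of every value.

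Of 54675 probe sets, 62 control probe sets were left out. Gene symbols came from the platform annotation given with the series. It listed 42892 of the remaining 54613 probe sets, 41091 with 1 symbol and 1801 with several, and 11721 were not listed and are unnamed here. Entrez identifiers of 41037 of the 41091 were found in the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols were not used in the tests of genes. A gene was represented by its probe set with the highest mean over all 8 arrays. Genes whose mean lay below the 40th percentile of all probe sets that were not controls (log2 4.70) were left out, which kept 14104 of 19775 genes. No reference sequence was used, so the planned search for miR-30 seed matches in untranslated regions was not run, and a list of reported miR-30 targets stood in for it.

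Genes were tested with limma 3.58.1 in R 4.3.3. A single fit of the 4 group means over all 8 arrays gave the difference between miR-30d and scrambled averaged over both lines, the same difference within each line, the difference between these responses (5B1 minus 4L), and the difference between 5B1 and 4L under the scrambled oligonucleotide. Each p was two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The fit had 4 residual and 3.33 prior degrees of freedom. Errors of fold changes are moderated standard errors (SE) on the log2 scale. The 13 gene lists had been written from general knowledge. They were tested with camera, which compares a list's genes with all others, at a preset correlation of 0.01 between genes; a correlation estimated from the arrays and fry, a rotation test, were alternatives. In both set tests p was two-sided and adjusted over the 13 lists. A list's median was also set among those of 10000 random lists of the same size and brightness.

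The labels number the repeats 1 and 2 in every group. Whether equal numbers pair the arrays was checked from the differences between repeats 1 and 2 across the tested genes. These differences correlated at 0.72 between scrambled and miR-30d arrays of 4L and at 0.66 in 5B1, and at 0.35 to 0.72 over all pairs of groups. Scrambled and miR-30d arrays with 1 number came from 1 cell line, and the 4 pairs of line and repeat deviated together, so the numbers were taken to pair the arrays. A second fit with the repeat as a block within each line had 2 residual and 3.84 prior degrees of freedom. It was an alternative to the fit without a block, and its values stand beside a result where they change the call or the count.

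Genes named in the text followed a rule. For the mean of both lines, and for 5B1 against 4L, it took the 10 largest rises and the 10 largest falls among genes that passed with arrays of both groups not overlapping in each line compared. For single lines and for the difference between the lines it took 5 and 5 chosen likewise, and where fewer passed, the genes with the smallest p, said not to pass. GALNT7, GALNT1 and IL10 were always named, and so were the 4 members of each list with the largest absolute change. With 2 arrays against 2 in each line, chance alone separates the groups in 1 direction in both lines for 5.56% of genes. Samples, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes singled out otherwise are said to have been chosen after their values were seen.

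The tests were tried on simulated data with the spread of the 14104 real genes and 100 genes changed by each size. For the mean of both lines, 76% of changes of log2 1 and 11% of changes of log2 0.5 were recovered without the block, and 86% and 54% with it. In 4L these shares were 32% and 0% without the block and 62% and 2% with it, and in 5B1 25% and 0%, and 59% and 4%. No unchanged gene was called (0 false calls) in any of these tests. A simulated list of 31 genes shifted by 0.4 passed the set test, and 0 of 12 other lists did. The simulated arrays carried the repeat deviations that the block models, and their other noise was independent between genes. Real genes can correlate, with an estimate of 0.085 for the interferon list. The simulation therefore cannot give the error rates of the block or of camera in these data.

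Alternatives were other filters on dim genes (none, or the 60th percentile), the average of a gene's probe sets, every probe set on its own, probe sets of the less specific kinds left out, a further quantile normalization, centring on the median, a prior variance with trend and robust estimation, the block, an additive model of line and treatment, fits of 1 line's arrays, other thresholds, and each array left out in turn. Added after seeing the data were a block shared by both lines, the block with an array left out, fits of each repeat alone, and the lists tested between the lines. Control probe sets for GAPDH, ACTB and 18S ribosomal RNA were read per array and entered no test of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.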

Results

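Messenger RNA levels were measured on 8 arrays of 2 human melanoma cell lines, 4L and 5B1, 48 h after transfection with a scrambled oligonucleotide or with miR-30d, a microRNA that represses transcripts carrying matches to its seed. Each of the 4 groups had 2 biological repeats, and 14104 genes were tested. The study's title names regulation of GalNAc transferases, the enzymes that start mucin-type O-glycosylation, in invasion and immunosuppression. The comparisons therefore ask which transcripts differ between miR-30d and scrambled cells, whether both lines respond alike, and how the lines differ without miR-30d.

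Transcripts of the housekeeping genes GAPDH and ACTB gave a sign of RNA quality on each array. Their control probe sets for the opposite transcript ends differed by 0.02 to 0.15 (log2) for GAPDH and by 0.91 to 1.39 for ACTB, whose difference was larger in repeat 1 than in repeat 2 in all 4 groups. The arrays of repeat 1 differed from those of repeat 2 in all 4 groups. The 5′ control probe set of 18S ribosomal RNA was higher in repeat 1 by 1.18 in 4L scrambled, 1.95 in 4L miR-30d, 1.59 in 5B1 scrambled and 1.61 in 5B1 miR-30d cells. The probe set for the middle of 18S was also higher in repeat 1, by 0.99 to 1.85, but the 3′ probe set was lower in repeat 1 in 4L (-0.55 and -0.30) and differed by 0.32 and 0.16 in 5B1. Between miR-30d and scrambled arrays of a pair the 5′ probe set differed by at most 0.53 in size. Each repeat held all 4 groups, so differences within repeats and with the repeat as a block could be given.

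**Figure D1:**
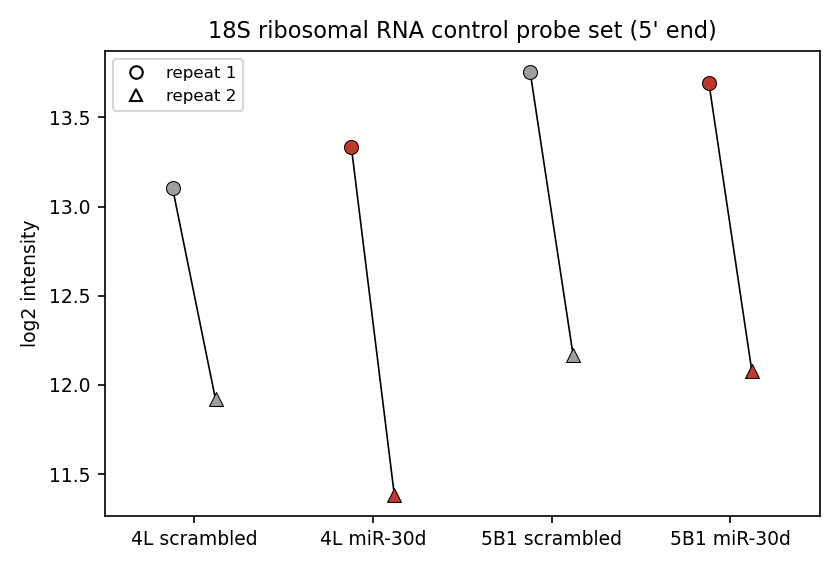
Log2 intensity of the 5′ control probe set of 18S ribosomal RNA (vertical axis) on each of the 8 arrays, by group (horizontal axis; grey, scrambled; red, miR-30d); circles are repeat 1, triangles repeat 2, and lines join the repeats of a group. Repeat 1 lies above repeat 2 in every group, by 1.18 to 1.95.

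GALNT7 and GALNT1, both GalNAc transferases, had lower transcript levels with miR-30d on average over the lines, and IL10, an immunosuppressive cytokine, had a higher level. GALNT7 stood at 62.9% of its scrambled level (log2 difference -0.67, SE 0.11) and GALNT1 at 67.3% (-0.57, SE 0.12), with 4 arrays on each side. Neither passed limma's test across all genes (adjusted p = 0.085 and 0.12), and both fell with the repeat as a block (adjusted p = 0.012 and 0.020). In 4L the mean log2 level of GALNT7 was 9.93 ± 0.23 (SD, n = 2) under scrambled and 9.27 ± 0.016 under miR-30d, and in 5B1 it was 10.21 ± 0.24 and 9.53 ± 0.13. GALNT1 went from 10.26 ± 0.36 to 9.64 ± 0.070 in 4L and from 10.15 ± 0.056 to 9.62 ± 0.011 in 5B1. IL10 differed by 0.76 (SE 0.17, adjusted p = 0.14), and rose with the block (adjusted p = 0.017). Its probe set was dim, with a mean log2 level of 5.38 against a filter at 4.70. Within repeat 1 alone the differences were -0.78, -0.70 and 0.63 for GALNT7, GALNT1 and IL10, and within repeat 2 they were -0.55, -0.44 and 0.89. Of the 5 probe sets of GALNT1, 4 were lower and 1 differed by 0.06, and both probe sets of GALNT7 were lower.

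**Figure D2:**
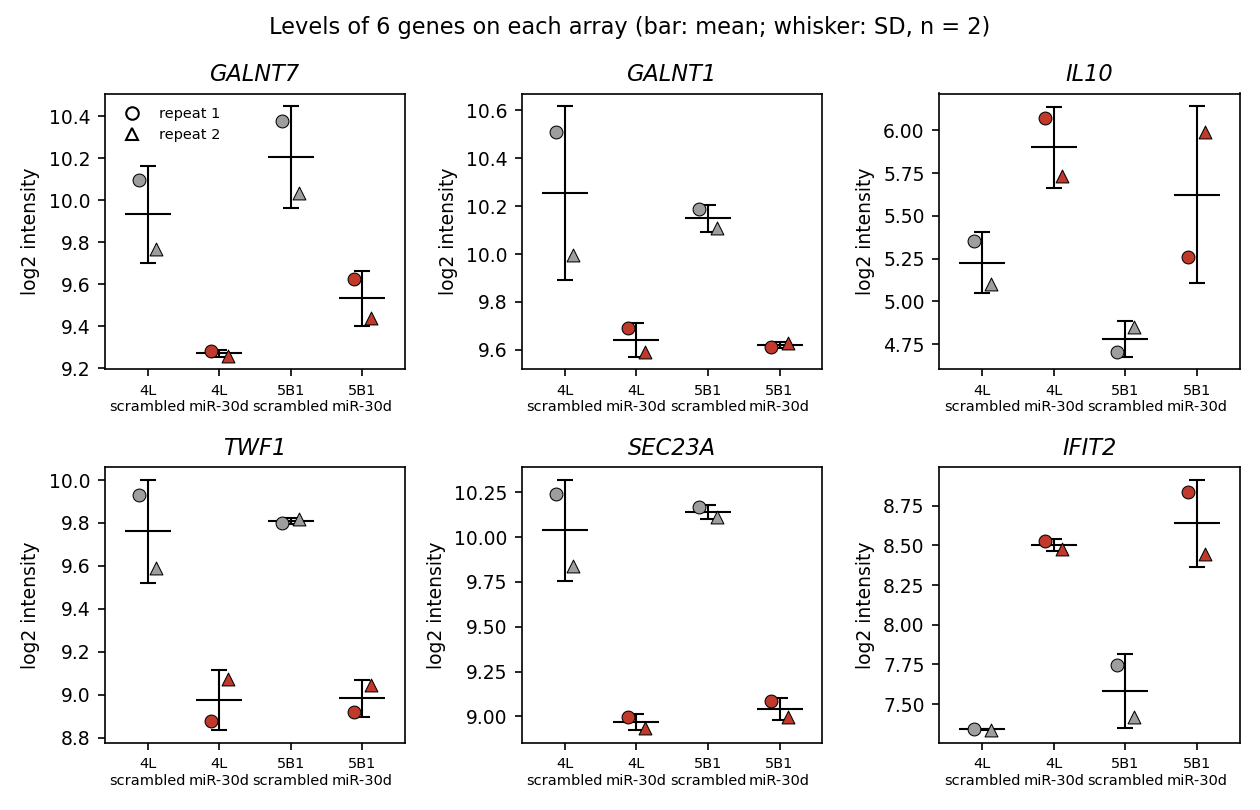
Log2 intensity (vertical axes) of GALNT7, GALNT1, IL10, TWF1, SEC23A and IFIT2 on each of the 8 arrays, by group (grey, scrambled; red, miR-30d); circles are repeat 1, triangles repeat 2, bars the group mean and whiskers the SD of 2 arrays. SEC23A and TWF1 are lower and IFIT2 is higher with miR-30d on every array of both lines.

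Averaged over both lines, 29 genes passed the test without the block, of which 11 rose and 18 fell with miR-30d. Among the falls were SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, at 47.1% of its scrambled level (log2 -1.08, SE 0.10, adjusted p = 0.035), and FAP, a cell-surface serine protease, at 47.0% (-1.09, SE 0.091, adjusted p = 0.032). SLC6A6, the taurine transporter, fell by 1.23 (SE 0.096, adjusted p = 0.032), CTSK, the protease cathepsin K, by 1.18 (SE 0.14, adjusted p = 0.043), and CD99, a surface glycoprotein, by 1.34 (SE 0.17, adjusted p = 0.046). The other large falls were those of KRTAP19-1 (-1.44), ZDHHC20, a palmitoyltransferase (-1.33), GPRIN3 (-1.14), PTGFRN (-1.08) and SPCS3, a subunit of the signal peptidase (-0.99), all with adjusted p of at most 0.046. The rises were led by IFIT2, an interferon-induced antiviral gene, at 216% of its scrambled level (log2 1.11, SE 0.12, adjusted p = 0.036). FNDC1 (1.09), CXADR, the receptor of coxsackieviruses and adenoviruses (1.00), MATCAP2 (0.90), ANKRD46 (0.87), LBH (0.83), DUSP5, a phosphatase of ERK kinases (0.77), ZBTB34 (0.76), CDKN1C, a cyclin-dependent kinase inhibitor (0.75), and DNAH9 (0.58) rose as well, with adjusted p of at most 0.048.

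All 29 genes differed in 1 direction in both lines and in 4 of 4 pairs of arrays. With the repeat as a block, 1099 genes passed, 637 of them higher and 462 lower, and these included the 29; with a block shared by both lines 385 passed. Of the 1099, 1098 had 1 direction in both lines and 1085 in 4 of 4 pairs. Both sets of genes were selected by their mean over these same arrays. Their agreement in direction therefore largely follows from the selection and is not separate support. SLC6A6 was measured by 3 probe sets above the filter, and 1 of them differed by 0.01, while the lowest response among the probe sets was -0.04 for SPCS3, -0.30 for ZDHHC20 and -0.32 for PTGFRN. The 2 probe sets of IFIT2 stood at 0.51 and 1.11, and the 3 of RPS6KA2, also among the 29, ran from -0.99 to -0.18. Without the block fewer genes passed whichever array was left out. Leaving out an array also lowers the residual degrees of freedom and widens the errors. The smaller counts alone therefore do not show dependence on single arrays. With the block the count also fell whichever array was left out. There the line that lost an array has no residual spread left, so the error comes from the other line alone, and dependence on a single array cannot be read from it.

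The transcripts reported as targets of the miR-30 family fell as a group. Of 38 measured, 31 were below 0, the median difference was -0.22, and camera gave an adjusted p of 1.2e-11 (adjusted p = 0.11 with an estimated correlation). TWF1, which binds actin monomers, fell by 0.81 (SE 0.10, adjusted p = 0.045), and the other 37 did not pass over all genes; adjusted over the list alone, 14 fell. With the repeat as a block, 15 fell and 0 rose. The largest differences besides TWF1 were those of RUNX2, a transcription factor of bone (-0.95, SE 0.18, adjusted p = 0.10, with 1 of its 3 probe sets at -0.07), AVEN, an inhibitor of apoptosis (-0.81, SE 0.19, adjusted p = 0.15), and NEDD4, a ubiquitin ligase (-0.80, SE 0.14, adjusted p = 0.086), and these 3 fell with the block. The median within repeat 1 was -0.25 and within repeat 2 -0.15. GALNT7, GALNT1, SEMA3A and TWF1 were put on this list with the study in mind, so their part of the count is not independent evidence. By fry, which tests whether a list's genes move on balance 1 way, the reported targets and the interferon genes passed (adjusted p = 0.014 for each), and neither did with the block (adjusted p = 0.070).

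Genes of the interferon response rose as a group. Of 31 measured, 30 were above 0, with a median difference of 0.44 and an adjusted p of 1.4e-17 (adjusted p = 0.076 with an estimated correlation). IFIT2 passed over all genes, 21 members rose adjusted over the list alone, and 15 rose with the repeat as a block. IFIT1 differed by 1.00 (SE 0.15, adjusted p = 0.072), OAS2, a sensor of double-stranded RNA, by 0.99 (SE 0.24, adjusted p = 0.15) and IFIT3 by 0.67 (SE 0.093, adjusted p = 0.055), and with the block these 3 rose. Also among the 15 were IRF7 (0.60), IFIH1 (0.57) and RIGI (0.37), which act in the recognition of viral RNA and the response to it. The 3 probe sets of OAS2 ran from 0.04 to 0.99. The median of the list was 0.52 within repeat 1 and 0.37 within repeat 2. In the same comparison the markers of other cell types (keratin, endothelial, fibroblast and blood cell genes) rose as a list, with 9 of 12 above 0, a median of 0.16 and an adjusted p of 0.017 (adjusted p = 0.20 with an estimated correlation). By fry these markers did not pass (adjusted p = 0.060), and over the alternatives their median ran from 0.08 to 0.24. Adjusted over the list alone 1 of them rose, and with the block the keratin KRT18 (0.35) and the matrix proteoglycan LUM (0.35) did; EPCAM differed by 0.51 (adjusted p = 0.29) and KDR by 0.24 (adjusted p = 0.87).

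Pigment cell markers fell as a list, with 12 of 17 below 0, a median of -0.13 and an adjusted p of 0.0034 (adjusted p = 0.55 with an estimated correlation). None passed over all genes, 2 fell adjusted over the list alone, and with the block PAX3, a transcription factor of the melanocyte lineage (-0.50), the endothelin receptor EDNRB (-0.47) and TRPM1 (-0.28) fell. RAB27A, which tethers melanosomes, differed by -0.21 (adjusted p = 0.53). Genes of cholesterol and fatty acid synthesis also fell as a list, with 16 of 19 below 0, a median of -0.11 and an adjusted p of 0.011 (adjusted p = 0.56 with an estimated correlation). None passed alone or adjusted over the list alone, and with the block LSS, which closes the sterol rings, fell by 0.33. INSIG2, ELOVL6 and SCD differed by -0.23, -0.22 and -0.19. Within repeats 1 and 2 the medians were -0.08 and -0.19 for the pigment cell markers and -0.02 and -0.16 for the lipid genes, and the markers of other cell types stood at 0.14 in both.

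The GalNAc transferases and core O-glycan enzymes did not shift together (adjusted p = 0.54). Their median was 0.07 and their mean -0.01, the sign camera gave. Over all genes 0 of 23 passed; 4 were lower and 1 was higher adjusted over the list alone, as with the block, and this list was chosen for the study's title. With the block GALNT3 (-0.78), GALNT7, GALNT1 and GALNT2 (-0.34) fell, and ST6GALNAC3, a sialyltransferase acting on O-glycans, rose (0.85).

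**Figure D3:**
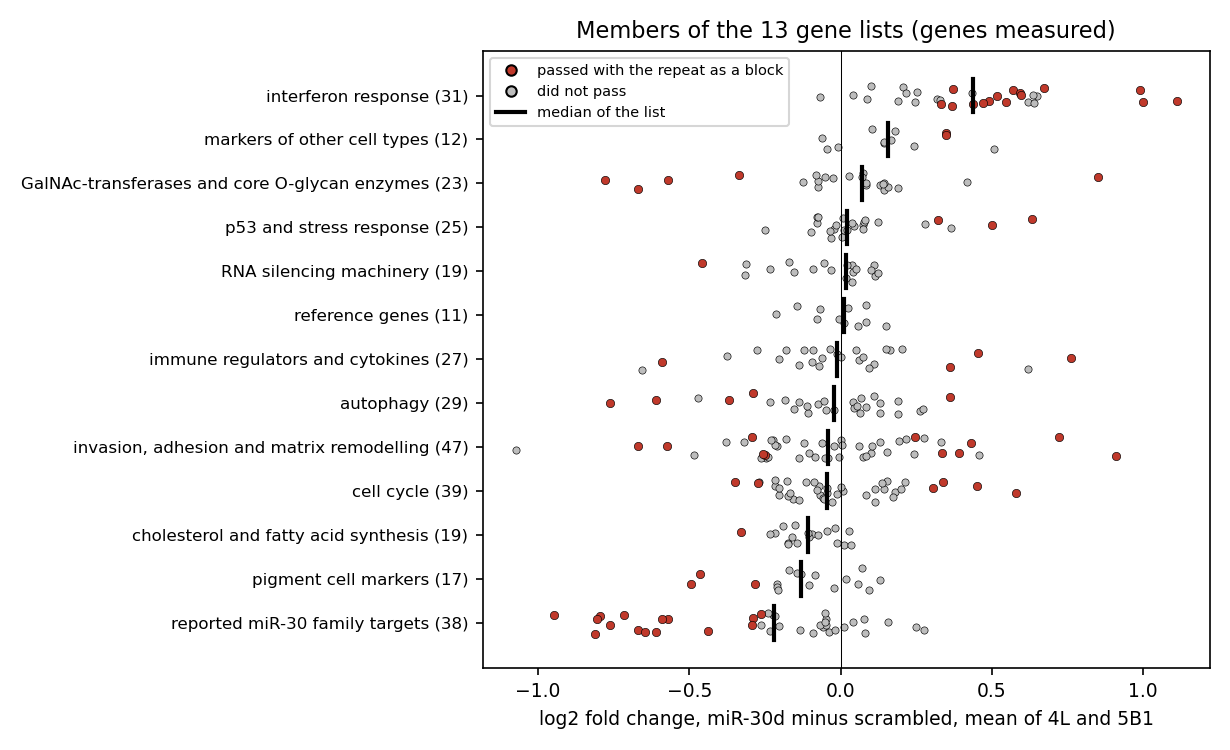
Log2 difference between miR-30d and scrambled cells averaged over 4L and 5B1 (horizontal axis) for each measured member of the 13 gene lists (vertical axis, number of genes in brackets); points are genes, red where they passed with the repeat as a block, and bars are medians. The medians run from -0.22 for the reported miR-30 targets to 0.44 for the interferon genes.

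By camera no other list passed. Against random lists of equal size and brightness, the medians of the invasion list (percentile 0.33) and of the cell cycle list (percentile 0.57) lay below the central 95%. Random lists leave out the correlation between a list's members, estimated at 0.0026 for invasion and 0.39 for the cell cycle. By fry neither list passed (adjusted p = 0.94 for each). In the remaining lists 0 members passed over all genes. Genes of invasion, adhesion and matrix remodelling had a median of -0.04 (adjusted p = 0.40 by camera). With every probe set tested on its own it was -0.05 (adjusted p = 0.0046), but probe sets of 1 gene then count as separate members. Of the 47 genes, 4 rose adjusted over the list alone. With the block 6 rose and 5 fell, among them PLAT, the tissue plasminogen activator (0.91), ZEB1, a repressor of epithelial genes (0.72), and MMP16, a membrane-bound metalloproteinase (-0.67), while MMP1 differed by -1.07 (SE 0.54, adjusted p = 0.55; -1.92 within repeat 1 and -0.22 within repeat 2). Of 27 immune regulators and cytokines (median -0.01 and mean 0.01, adjusted p = 0.76), 2 rose and 1 fell adjusted over the list alone. With the block IL10, CD276 (0.45) and ULBP2 (0.36) rose and NT5E, which makes adenosine, fell (-0.59), while CXCL8 differed by -0.66 (adjusted p = 0.48) and CCL5 by 0.62 (adjusted p = 0.37). Within repeat 1 these 2 cytokines differed by -1.16 and 1.02, and within repeat 2 by -0.16 and 0.22. The 4 probe sets of NT5E ran from -1.86 to -0.48, and 1 of 3 of MMP16 differed by 0.08. NT5E is also on the list of reported miR-30 targets, so its fall is not separate evidence.

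Among 39 cell cycle genes (median -0.05, adjusted p = 0.47; -0.11 and adjusted p = 0.017 without 4L scrambled repeat 2) 1 rose adjusted over the list alone, and with the block E2F2 (0.58), CCNE1 (0.45), CDC25A (0.34) and CCND1 (0.31) rose and KIF11 (-0.35) and CCNB2 (-0.27) fell; 1 of 3 probe sets of E2F2 differed by -0.01. Among 25 genes of the p53 and stress response (median 0.02, adjusted p = 0.40) 1 rose adjusted over the list alone, and with the block PMAIP1, a pro-apoptotic gene (0.63), HMOX1 (0.50) and DNAJB9 (0.32) rose; TP53I3 differed by 0.36 (adjusted p = 0.50). Of 29 autophagy genes (median -0.02, adjusted p = 0.40) 1 rose and 1 fell adjusted over the list alone. With the block ATG12 (-0.76), BNIP3L (-0.61), WIPI1 (-0.37) and ATG5 (-0.29) fell and ULK2 (0.36) rose, and BNIP3 differed by -0.47 (adjusted p = 0.81). ATG12, BNIP3L and ATG5 are also on the list of reported miR-30 targets, so their falls are not separate evidence. Over the alternatives BNIP3L ran from -0.91 to -0.31 and BNIP3 from -0.94 to -0.0035. Of 19 genes of the RNA silencing machinery (median 0.02 and mean -0.06, adjusted p = 0.13) 1 fell adjusted over the list alone, and with the block this held for TNRC6B, a scaffold of the silencing complex (-0.46). This list passed with averaged probe sets (median -0.04, adjusted p = 0.030), with every probe set tested on its own (-0.11, adjusted p = 6.2e-05) and without 5B1 scrambled repeat 2 (-0.06, adjusted p = 0.015). With every probe set on its own, TNRC6B entered with 7 probe sets and TNRC6A with 6. Camera counted these as separate members at a correlation of 0.01, so the adjusted p in that setting can be too small. TNRC6A, AGO2 and MOV10 differed by -0.32, -0.31 and -0.23. Of 11 reference genes (median 0.01 and mean -0.01, adjusted p = 0.69) none passed in any of these ways; the largest differences were those of YWHAZ (-0.21), GUSB (0.15), TFRC (-0.14) and HPRT1 (0.09).

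Within 4L, the genes with the smallest p were CDKN1C (0.85), IFIT2 (1.16), PTPRG (0.83), IL15RA, a subunit of the interleukin-15 receptor (0.77), and ANKRD46 (0.94), all higher with miR-30d, and SLC6A6 (-1.26), RPS6KA2, a kinase downstream of ERK (-0.96), SEC23A (-1.07), ZDHHC20 (-1.43) and PTGFRN (-1.13), all lower. Their SE ran from 0.12 to 0.19, and none passed limma's test without the block (smallest adjusted p = 0.25). With the block 99 genes passed in 4L, 52 higher and 47 lower, and these 10 were among them; with a block shared by both lines 17 passed. GALNT7 (-0.66), GALNT1 (-0.61) and IL10 (0.68) did not pass in 4L in either fit, with adjusted p of 0.057, 0.072 and 0.089 with the block. Without the block 0 of 14104 genes passed in 4L, and 946 had an unadjusted p under 0.05. With the block 448 passed when any 1 of the 5B1 arrays was left out, and 0 when any 1 of the 4L arrays was. As lists, the reported miR-30 targets (median -0.25, adjusted p = 1.5e-11; 9 fell adjusted over the list alone) and pigment cell markers (-0.12, adjusted p = 0.013) fell in 4L, and interferon genes (0.48, adjusted p = 4.5e-20; 16 rose adjusted over the list alone) and markers of other cell types (0.15, adjusted p = 0.030) rose. None of these calls held with an estimated correlation (adjusted p = 0.11, 0.63, 0.060 and 0.22), and genes of cholesterol and fatty acid synthesis (-0.08) passed with the block alone (adjusted p = 0.025; adjusted p = 0.80 with an estimated correlation).

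Within 5B1, NMNAT1, an enzyme of NAD synthesis (0.79), CXADR (1.19), FNDC1 (1.23), IFIT2 (1.06) and DUSP5 (0.87) were higher with miR-30d and FAP (-1.27), SLC6A6 (-1.19), RPS6KA2 (-1.01), SEC23A (-1.10) and SLC6A15, an amino acid transporter (-0.83), lower. These had the smallest p and did not pass without the block (smallest adjusted p = 0.17; SE 0.095 to 0.18). With the block 19 genes passed, 11 higher and 8 lower, among them NMNAT1, IFIT2, FAP, SLC6A6, RPS6KA2 and SEC23A (adjusted p = 0.045 for each), and with a block shared by both lines 1 gene passed. GALNT7 (-0.67), GALNT1 (-0.53) and IL10 (0.84) did not pass in 5B1 in either fit, with adjusted p of 0.071, 0.12 and 0.085 with the block. Without it 0 genes passed, and 766 had an unadjusted p under 0.05. With the block 104 passed when either repeat 2 array of 5B1 was left out, and 0 when any other array was. The lists of reported miR-30 targets (median -0.19, adjusted p = 1.4e-09), pigment cell markers (-0.09, adjusted p = 0.0069) and cholesterol and fatty acid synthesis (-0.12, adjusted p = 0.0069) fell in 5B1, and interferon genes (0.34, adjusted p = 2.5e-10) and markers of other cell types (0.17, adjusted p = 0.047) rose. With an estimated correlation none of these 5 calls held (adjusted p = 0.15, 0.43, 0.55, 0.15 and 0.29). Adjusted over the list alone, 7 reported targets fell and 2 interferon genes rose.

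No gene was shown to respond differently in the lines. The smallest p belonged to CCL17, a chemokine (response in 5B1 minus that in 4L 0.95, SE 0.23), CARNS1 (0.59), CRYAB, a small heat shock protein (0.73), NMNAT1 (0.48) and ITPKC (0.53), and on the other side to IL15RA (-0.71), CST9 (-0.83), ST8SIA5 (-0.62), ARMC5 (-0.50) and LYPD3 (-0.48). With limma 0 of 14104 genes passed without or with the block (smallest adjusted p = 1.00 and 0.97), and 114 and 662 had an unadjusted p under 0.05. For GALNT7, GALNT1 and IL10 the difference was -0.01 (SE 0.23), 0.09 (SE 0.24) and 0.17 (SE 0.34). Across genes, which are not independent replicates, the responses of the lines correlated with Pearson's r = 0.65 and Spearman's rho = 0.54, and the lines shared no array; r was 0.46 within repeat 1 and 0.57 within repeat 2. Of the genes that passed with the block in single lines, 9 rose in both and 7 fell in both; the fit pools the variance of a gene over the lines, so the calls in the lines are not independent. By camera at the preset correlation the interferon list alone responded differently, with a median difference of -0.17, the response being lower in 5B1 (adjusted p = 2.0e-06, or 0.43 with an estimated correlation). By fry it did not pass (adjusted p = 0.97), and 0 of its members passed adjusted over the list alone.

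**Figure D4:**
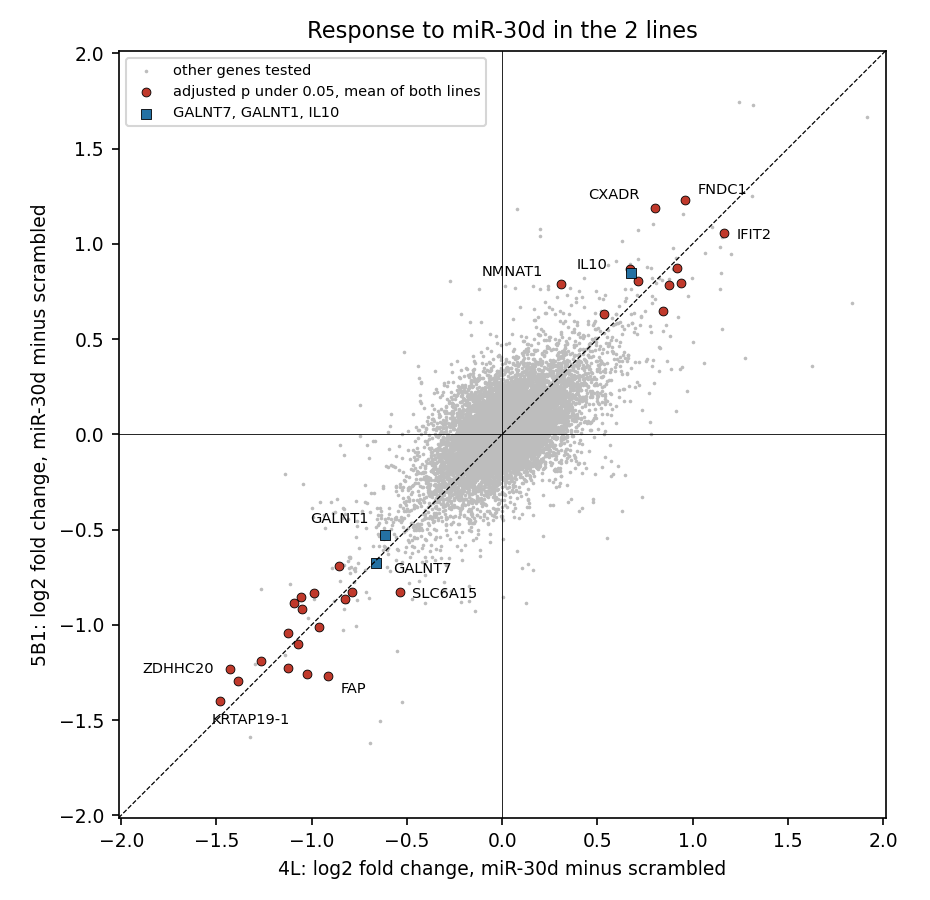
Log2 fold change of miR-30d over scrambled in 4L (horizontal axis) and in 5B1 (vertical axis) for the 14104 genes tested; red points are the 29 genes that passed for the mean of both lines without the block, blue squares are GALNT7, GALNT1 and IL10, and the dashed line marks equal responses. All 29 red points lie in the quadrants of equal sign, which their selection by the mean of both lines makes likely. Across all genes r is 0.65.

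Without miR-30d the lines differed in 74 genes, 45 higher in 5B1 and 29 higher in 4L. Higher in 5B1 under the scrambled oligonucleotide were TMEM132D-AS1, an antisense RNA (log2 4.32, SE 0.38), CHST9, a sulfotransferase (log2 3.78, SE 0.38), ADGRG2, an adhesion receptor (3.06), ART3 (2.94), NUPR1, a stress-induced nuclear protein (2.90), TMEM204 (2.81), GTSF1 (2.62), GPR143, a receptor of melanosomes (2.47), QPCT (2.44) and PLBD1 (2.41). Higher in 4L were the noncoding RNA LINC00698 (log2 -4.06, SE 0.19), TGFA, a ligand of the EGF receptor (7.66-fold, log2 -2.94, SE 0.36), CACNA2D4 (-2.53), THBS2, a matrix glycoprotein (-2.45), the cytokine LIF (-2.03), BMPR1B (-2.03), ZIC2 (-1.91), RASGRF1 (-1.81), PRTFDC1 (-1.77) and OVAAL (-1.62). These 20 genes had adjusted p from 0.00099 to 0.034, with n = 2 arrays in each line. In the line with less of them, CHST9 (log2 level 3.75), ADGRG2 (4.67) and LINC00698 (4.55) lay below the filter on dim genes at 4.70, so the size of these 3 differences depends on the background. ART3 was also lower with miR-30d (-1.46, adjusted p = 0.085), and fell with the block (adjusted p = 0.017).

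Pigment cell markers were higher in 5B1 as a list (median 0.09, mean 0.36, adjusted p = 0.00012), and so were interferon genes (median 0.22, adjusted p = 9.4e-07) and genes of cholesterol and fatty acid synthesis (median 0.13, adjusted p = 0.015). With an estimated correlation none of these 3 calls held (adjusted p = 0.43, 0.40 and 0.66), and the test of lists between the lines was added after seeing the data. Of the pigment cell markers 3 passed over all genes, GPR143, EDNRB (1.12) and TRPM1 (1.08), and 5 adjusted over the list alone. No interferon gene passed over all genes, and 1 did adjusted over the list alone. The other 10 lists did not pass by camera. Among their members SNAI2, a repressor of epithelial genes, was higher in 5B1 (1.03, adjusted p = 0.026), and MCAM, a melanoma adhesion molecule (-0.89, adjusted p = 0.038), and LIF were higher in 4L. Without the block 14 genes passed when 4L scrambled repeat 1 was left out, 24 without 4L scrambled repeat 2, 27 without 5B1 scrambled repeat 1, 49 without 5B1 scrambled repeat 2 and 48 without either miR-30d array of 4L. With the repeat as a block within each line 663 genes passed, but this block takes out the spread of the repeats against which lines are compared and understates the error; with a block shared by both lines 195 passed.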

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

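The tests chosen only after the result was seen are the correlation of the repeats, the ribosomal RNA signal and the splits that part the pairs with the block.

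By camera at the preset correlation, the response of the interferon list differed between the lines (adjusted p = 2.0e-06, or 0.43 with an estimated correlation). The median was -0.17 (5B1 minus 4L) over 31 genes, 24 of them below 0. By fry the list did not pass (adjusted p = 0.97, and 0.80 with the block), and 0 members passed adjusted over the list alone. The scrambled arrays, on which the list was higher in 5B1 (median 0.22), enter this difference with the opposite sign.

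Interferon genes were higher with miR-30d in both lines. Of 34 splits of the 8 arrays into 4 and 4, the split by line left out, only the real 1 gave a median as far from 0 (0.44, against 0.35 for the highest other), but most of them mix arrays that the repeats pair, and the 8 splits that part all 4 pairs (0.44 against 0.29) are too few for a share under 0.05. Each repeat held both treatments, so a difference between the repeats shared by both cancels within a repeat and cannot give the direction. The design settles this, and the medians within the repeats add no test of it. They were 0.37 and 0.52 (bootstrap SE 0.083 and 0.051), both beyond the bound set beforehand. Brightness of the probe sets is argued against by the list's rank at percentile 100 of 10000 random lists. Lower SOCS1 and SOCS3, which restrain interferon signalling, stay open, since their differences of 0.078 (SE 0.068) and 0.012 (SE 0.061) come from dim probe sets (log2 5.10 and 5.34 against a filter at 4.70) that could hide a fall, which the bound set before the test had not considered. Also open is whether the response belongs to the activity of miR-30d or may come from a different recognition of the transfected oligonucleotides as foreign RNA, since a single scrambled oligonucleotide was the control and no test here separates these.

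Reported miR-30 targets were lower with miR-30d. Of 34 splits 1, the real 1, gave a median as far from 0 (0.22 in size, against 0.19 for the highest other), and the 8 splits that part all 4 pairs (0.22 against 0.12) are again too few for a share under 0.05. Brightness of the probe sets is argued against by percentile 0 of 10000 random lists, and a list that only follows GALNT7, GALNT1, SEMA3A and TWF1, set aside beforehand as targets that the study may itself have reported, by percentile 0 again without these 4 (34 genes, median -0.17). A difference between the repeats that both treatments share cancels within a repeat, so it cannot give the direction. The median was -0.25 within repeat 1 and -0.15 within repeat 2 (bootstrap SE 0.091). In repeat 2 it was not beyond -0.1 by more than its error, the bound set beforehand. That bound did not compare the repeats with each other, and whether the response was smaller in repeat 2 was not tested. Direct repression by miR-30d may account for the direction, a hypothesis that seed matches in the transcripts would test and that was not tested here.

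More genes passed for the mean of both lines with the repeat as a block, 1099 against 29. Splits were counted without a block in the additive model, which called 143 genes where the main fit called 29. As many genes came from 2 of 34 splits, the real 1 with 143 and the split of repeat 1 against repeat 2 with 1017. No other split gave any gene, and the 1017 point to a structure of the arrays by repeat. By the share of 0.05 set beforehand, chance cannot be excluded for this count. Among the 8 splits that part all 4 pairs, fitted with a term for each pair and a single treatment term (3 residual degrees of freedom, where the block by line with separate responses has 2), the real 1 gave 1362 genes and the highest other 0; the others swap the treatments within some pairs, and 8 splits are too few for a share under 0.05. Repeat-specific conditions shared by both treatments are consistent with the correlations of the repeat differences, the lower of which was 0.66. Whether the ribosomal RNA signal is their source cannot be told apart from other differences between the repeats: the 5′ control probe set of 18S differed by at least 1.18 between repeats and by up to 0.53 between treatments, the 3′ probe set went the other way in 4L (-0.55 and -0.30) and not in 5B1 (0.32 and 0.16), and with 2 repeats anything else that differed between them would vary alike.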

How the results depend on the processing

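The block shared by both lines, the fits of each repeat alone, the block with an array left out and the list tests between the lines were tests chosen only after the results were seen.

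For the mean of both lines (29 genes), 47 genes passed with a filter at the 60th percentile, 14 with averaged probe sets (10 of the 29), 4 with every probe set on its own, 67 with a trended and robust prior, 128 at an adjusted p under 0.1 and 143 with the additive model (28 of the 29). The block by line gave 1099 and the block shared by both lines 385, each with all 29, repeat 1 alone gave 1 and repeat 2 alone 458 (28 of the 29). Testing every probe set means more tests. In the list tests it also counts probe sets of 1 gene as separate members, so the adjusted p can be too small. For the other alternatives the cause was not tested. With no filter, less specific probe sets left out, a further quantile normalization, median centring or a 1.5-fold minimum, 24 to 37 genes passed.

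In 4L (0 genes) the block by line gave 99 and the shared block 17, and in 5B1 (0 genes) 19 and 1. Between the lines under the scrambled oligonucleotide (74 genes) they gave 663 and 195, where the block by line understates the error, since it takes out the spread of the repeats within a line. No alternative gave a gene whose response differed between the lines (0 throughout with limma; 114 genes at an unadjusted p under 0.05 without and 662 with the block). Fits of a line's own 4 arrays gave 0 genes in either line, with 757 (4L) and 845 (5B1) at an unadjusted p under 0.05. The cause was not tested.

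With an array left out and no block, the lone array of its group is assumed to vary like the others. With the block by line, the line that lost an array has no residual spread left, and the error comes from the other line alone. Leaving out either array of a pair then gives the same comparison of miR-30d with scrambled, so those counts do not show dependence on single arrays. The counts ran from 0 to 13 without the block and from 0 to 780 with it for the mean of both lines, from 0 to 448 with it in 4L, and from 0 to 104 with it in 5B1; without it they were 0 in both lines. Between the lines they ran from 14 to 54 without and from 52 to 926 with the block (52 without 4L scrambled repeat 1, 65 without 4L scrambled repeat 2, 299 without either miR-30d array of 4L, 321 without 5B1 scrambled repeat 1). The 5 list calls became 7 with every probe set on its own (RNA silencing gained, and invasion at -0.054, adjusted p 0.0046), 6 with averaged probe sets, 4 with no filter, with the filter at the 60th percentile or without the less specific probe sets, 3 in repeat 1 alone, 0 with an estimated correlation and 2 by fry (interferon genes and reported targets), and 3 to 6 with an array left out, 3 without 4L scrambled repeat 2 (the cell cycle gained, adjusted p 0.017) or 5B1 scrambled repeat 1.

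GALNT7 ran from -0.78 to -0.55 (adjusted p 0.012 to 0.32), GALNT1 from -0.70 to -0.44 (0.020 to 0.39) and IL10 from 0.58 to 0.94 (0.017 to 0.41). The interferon list's median ran from 0.36 to 0.52 and that of the reported targets from -0.25 to -0.13. For single genes and lists with no array left out, 864 and 151 values kept their direction and side of the threshold, 119 and 1 came to pass, 58 and 13 no longer passed, and 1 and 17 reversed their sign. With an array left out these numbers were 403 and 84, 1 and 1, 160 and 7, and 4 and 12. The reversed values all belonged to genes and lists that had not passed, and their cause was not tested.

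With averaged probe sets HPRT1 and the median of the reference genes stood at -0.00019, the RNA silencing list at -0.042 (adjusted p 0.030, the range over its alternatives reaching down to 6.2e-05) and autophagy at 0.0033. With every probe set on its own the RNA silencing list stood at -0.11 (adjusted p 6.2e-05) and the reference genes at -0.023. Without the less specific probe sets these lists stood at -0.019 and -0.048, and autophagy at 0.0099. The immune list stood at 0.0020 with no filter, 0.0029 with a further quantile normalization and 0.0046 with median centring. In repeat 1 alone RNA silencing stood at -0.013, the immune list at 0.074, invasion at 0.0042 and autophagy at 0.00066, and in repeat 2 alone the immune list stood at 0.018 and the reference genes at -0.010. With an array left out INSIG2 ran from -0.49 to 0.022, ELOVL6 from -0.45 to 0.013, KDR from -0.10 to 0.59, and the medians of the GalNAc enzymes from -0.025 to 0.049, RNA silencing from -0.064 (adjusted p 0.015, without 5B1 scrambled repeat 2) to 0.049, the immune list from -0.017 to 0.053, invasion from -0.11 to 0.0060, the cell cycle from -0.11 to 0.032 and autophagy from -0.060 to 0.015.

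Seed matches, and with them the restriction to the strongest sites and the bins of transcript length, were not run for want of transcript sequence. The number of arrays limits what can pass: in the simulation without the block, 11% of changes of log2 0.5 were recovered for the mean of both lines and 0% within a line.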

Other observations

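The families of gene symbols and the single genes below were tested or chosen only after their values were seen.

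Among 5989 probe sets above the filter without exactly 1 gene symbol (unnamed or with several), limma called 0 for the mean of both lines, without or with the block. Gene families with a shared symbol stem and at least 10 measured members numbered 177. With camera 0 of them passed without or with the block, and 11 had an unadjusted p under 0.05. The symbols beginning with COL (27 genes, among them the antisense RNA COL18A1-AS1) had a median of 0.11 (adjusted p = 0.73), and 6 members rose with the block and 0 fell: COL4A5 (1.09), COL4A1 (0.67), COL18A1 (0.58), COL4A2 (0.39), COL9A2 (0.32) and COL22A1 (0.29). Each of the 6 was higher in 4 of 4 pairs of arrays, which passing with the block makes likely. SERPINH1, a chaperone of collagen folding, differed by 0.75 (adjusted p = 0.34 without and 0.0080 with the block). The symbols beginning with ALDH (16 genes, among them the antisense RNA ALDH1L1-AS2) had a median of 0.10 (adjusted p = 0.32), and ALDH1A3 (0.53), ALDH6A1 (0.37), ALDH9A1 (0.32), ALDH7A1 (0.30) and ALDH5A1 (0.26) rose with the block.

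Some of the largest differences belonged to genes that passed with the block alone. SERPINA3, a protease inhibitor of the acute phase, differed by 1.79 (SE 0.44, adjusted p = 0.16 without the block; SE 0.16, adjusted p = 0.010 with it). KCNJ2, a potassium channel, differed by 1.52 (adjusted p = 0.078 and 0.0060), and SLC22A4, a transporter of organic cations, by 1.49 (adjusted p = 0.098 and 0.0090). TNFRSF21, a death receptor, differed by 1.07 (adjusted p = 0.10 and 0.0078). Lower with miR-30d were NEFL, a neurofilament protein (-1.15, adjusted p = 0.12 and 0.0095), and HDAC9, a histone deacetylase (-1.04, adjusted p = 0.073 and 0.0078). All 6 had 1 direction in 4 of 4 pairs, as did 1085 of the 1099 genes that passed with the block. This agreement largely follows from the selection.

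Other single genes passed with the block alone. B3GNT5, which extends glycolipids (-0.82, adjusted p = 0.085 and 0.012), and POGLUT3, which adds glucose to proteins (-0.78, adjusted p = 0.11 and 0.016), were lower with miR-30d. MGAT4A, which branches N-glycans, was higher (1.09, adjusted p = 0.18 and 0.021). NPC1, which exports cholesterol from lysosomes, was lower (-0.72, adjusted p = 0.056 and 0.012).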
